A study of Mus musculus with 9 samples.

How the data were processed

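Per the labels' protocols, ovaries were digested with trypsin, EDTA and DNase into single cells for 10x Genomics libraries. Per the submitters' processing notes the reads were processed with Cell Ranger, version 3.1.0 per the file headers, and the deposited matrices hold raw UMI counts per gene and cell barcode, in the unit counts per the file headers, with no normalization and with called barcodes only. The genome build the authors used is not given in the sources used here. Of 31053 gene identifiers in the files, 30934 match GENCODE M21 on GRCm38, from which positions were taken. The library at P1 and 2 libraries each at D14, W8, M8 and M12 were grouped by the labels, which give no batch or animal.

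The gene lists, tests, filters, alternatives and the rule for named genes were chosen before the data were examined. Barcodes were kept with at least 500 detected genes and at most 20% of UMIs from mitochondrial genes. Barcodes with the highest Scrublet scores were removed after clustering, 0.8% per 1000 barcodes of the library (3.11 to 18.7%). Of 115283 barcodes, 89865 were kept, 3242 at P1 to 17925 in M8 replicate 2. Barcodes past the other filters were scaled to 10000 UMIs and clustered together by Leiden at resolution 1 (2500 variable genes, 40 principal components, 20 neighbours), giving 38 clusters (54 at resolution 2). A cluster was named by its markers, with at least 3 markers detected in at least 10% of its cells and at least log2 1 above other cells, or stayed unnamed. Scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used in Python 3.11.15.

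UMI counts were summed per library and class. Granulosa, theca, stromal, blood endothelial, and macrophage and monocyte classes were fitted over the 8 libraries of D14 to M12, and luteal cells over the 6 libraries of W8 to M12, since D14 holds too few. Each library had to hold at least 20 cells of the class. Genes were tested with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood F-test, two-sided) in R 4.3.3, and p-values were adjusted by Benjamini and Hochberg within each class and comparison, with a threshold of 0.05. Main comparisons are W8 minus D14 and M12 minus W8, while M8 minus W8 and M12 minus M8 are given as sums over classes. A log2 change is relative to the TMM scaling. Class shares were tested with edgeR on numbers of cells over all kept cells, for 14 classes, leaving out germ cells, whose number the preparation sets, and unnamed clusters. With 2 libraries per age, all ages shared 1 estimate of the spread, with a biological coefficient of variation of 0.0661 to 0.155, and no split of samples was tested.

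There were 18 gene lists: steroid hormone synthesis (20 genes), cholesterol synthesis and uptake (23), extracellular matrix and collagen (32), inflammatory cytokines and chemokines (28), senescence and secretory phenotype (25), cell cycle (30), oxidative phosphorylation (51 of 66 symbols in the files, the others being newer names), antioxidant and metallothionein (29), immediate early and heat shock (27), unfolded protein response (22), interferon response (25), antigen presentation (18), the transforming growth factor beta family in follicles (29), ribosomal proteins (84), and RNA of germ cells (16), red cells (5), immune cells (15) and follicle and luteal cells (13) that is foreign to other classes. They were tested with camera on voom values (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the list and class tests of a comparison, with at least 5 genes measured. Of 89 tests of W8 minus D14, 68 passed (58 up and 10 down), and of 107 of M12 minus W8, 58 passed (13 up and 45 down). None passed with a correlation estimated per list, where the smallest adjusted p was 0.12 and 0.362. With fry, which tests whether genes move on balance one way, 53 and 36 passed.

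Named genes are, per class and main comparison, the 3 with the highest and the 3 with the lowest log2 change among genes past the test with at least 50 CPM in the higher group and libraries that do not overlap, passing over predicted genes, Xist and mitochondrial genes, plus up to 4 members with the smallest adjusted p of each list called. Some genes this rule picks are not reported here. For P1, the 5 highest and 5 lowest ratios to D14 among genes of at least 100 CPM are named. Genes at 0 in a group are given against 3 counts over the group, and genes with 1 to 3 counts with a counting interval. Intervals cover counting error only.

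Alternatives were DESeq2 1.42.0, RLE size factors, no filter on counts, a replicate block, at most 10% mitochondrial UMIs, at least 1000 genes, doublets kept, resolution 2, class sums thinned to equal depth, each library left out in turn, and, for shares, TMM over classes and limma on centred log ratios. Chosen after the data were examined were 3 more: leaving out low-UMI clusters with over 50% of their cells from M8 replicate 2, leaving out both M8 libraries, and using 1 cluster per class shared by W8 and M12. On simulated data with 200 changed genes in the M12 minus W8 design, edgeR found 65.7% of genes changed 1.5-fold in granulosa, 44.8% in theca, 41.8% in luteal, 77.6% in stromal, 10.4% in endothelial cells and 4.48% in macrophages, and 84.8%, 72.7%, 68.2%, 90.9%, 50% and 45.5% of genes changed 2-fold, with 7 to 13 false calls. P1 was left out of all tests, having 1 library.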

Results

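Ovaries of C57BL/6J mice were profiled by droplet single-cell RNA sequencing (10x Genomics) at 5 ages, in 9 libraries. Postnatal day 1 (P1) has 1 library of germ and somatic cells. Day 14 (D14), week 8 (W8), month 8 (M8) and month 12 (M12) have 2 libraries each, described as somatic cells. The P1 library held 38166102 UMIs. The 2 libraries of D14 held 163000849 and 129685629, those of W8 147675229 and 147499793, those of M8 112714639 and 106989487, and those of M12 106138564 and 95869724. Median UMIs per barcode lay between 7162 and 8487, except at M8 with 4186 and 1937. Of 115283 barcodes, 89865 were kept and sorted into cell classes by marker genes. The labels do not say whether the 2 libraries of an age come from separate animals. Adjusted p-values therefore measure only the spread between these libraries. Gene levels are CPM of a class, as mean ± SD of n = 2 libraries, the later age first. Log2 changes are given ± SE, and gene positions are on GRCm38.

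The P1 comparison describes the newborn ovary beside the D14 ovary. Stromal cells made up 38.7% (37.1 to 40.4) of the 3242 barcodes kept at P1 (95% Clopper-Pearson interval). Erythroid cells were 23.1% (21.7 to 24.6), epithelial cells 17.4% (16.1 to 18.7) and germ cells 14.3% (13.1 to 15.6). The epithelial cells are cluster 4, called on 5 markers, none among its top genes (such as H19, Rmst and Rspo1), so the name is uncertain. Barcodes called granulosa were 3, 0.0925% (0.0191 to 0.27), and cluster 4 may hold more granulosa cells. No barcode was called theca or luteal, which allows up to 0.114% for each. With at least 1000 genes, stromal, erythroid and germ cells were 43.9%, 20.3% and 11%. Epithelial cells were 15.1% with at most 10% mitochondrial UMIs.

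Of 16 germ cell markers, 8 stood higher in P1 germ cells than in both D14 libraries, 7 lower, and Uchl1 between. P1 germ cells lay in cluster 14 (464 cells). Those of D14 lay mostly in cluster 20 (1696 and 2521 cells, relative UMI count 0.112), with 3 and 45 in cluster 34 (1.106). D14 values are thus mostly of low-UMI barcodes and may not be oocyte levels. In CPM at P1 against D14, Sycp3, a protein of the meiotic chromosome axis, was at 1521 (1485 to 1558) against 107 and 67.4. Figla, a transcription factor of primordial follicle formation, was at 1124 (1093 to 1155) against 115 and 126. Dazl, an RNA-binding protein of germ cells, was at 718 (694 to 744) against 147 and 302. Zp3, a protein of the egg coat, was at 26.8 (22.2 to 32.1) against 1608 and 6517. Gdf9, an oocyte growth factor, was at 22.8 (18.6 to 27.7) against 504 and 2151. Oosp1 had no count at P1, which allows up to 0.824, against 183 and 651.

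Among stromal cells, the largest P1 cluster (3, 1256 cells) was set beside the largest D14 cluster (30, 5185 and 3316 cells). The imprinted genes H19, Dlk1 and Meg3 had the highest ratios of P1 to D14. H19 was at 1391 CPM (1369 to 1414) at P1 against 2.32 and 5.01 CPM at D14, 379 times as high. Dlk1 was at 1909 CPM (1883 to 1936) at P1 against 6.07 and 11.4 CPM at D14, 219 times as high, and Meg3 at 4199 CPM (4159 to 4239) at P1 against 26.3 and 29.8 CPM at D14, 149.7 times as high. Next came the globin genes Hba-a2 (63.9 times) and Hba-a1 (48.5 times), which are red cell RNA and near-identical copies. At the other end was Tmem100, a membrane protein, at 14.3 CPM (12.1 to 16.8) at P1 against 635 and 454 CPM at D14. Ptch1, the receptor of hedgehog signals, was at 9.7 CPM (7.88 to 11.8) at P1 against 397 and 303 CPM at D14. Also lower at P1 were the germ cell marker Ooep (286 times) and the granulosa markers Inha (41.1 times) and Greb1 (31.9 times). P1 has no replicate, so these values carry counting intervals (exact Poisson, 95%) and no test. P1 granulosa cells were too few to compare.

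**Figure D1:**
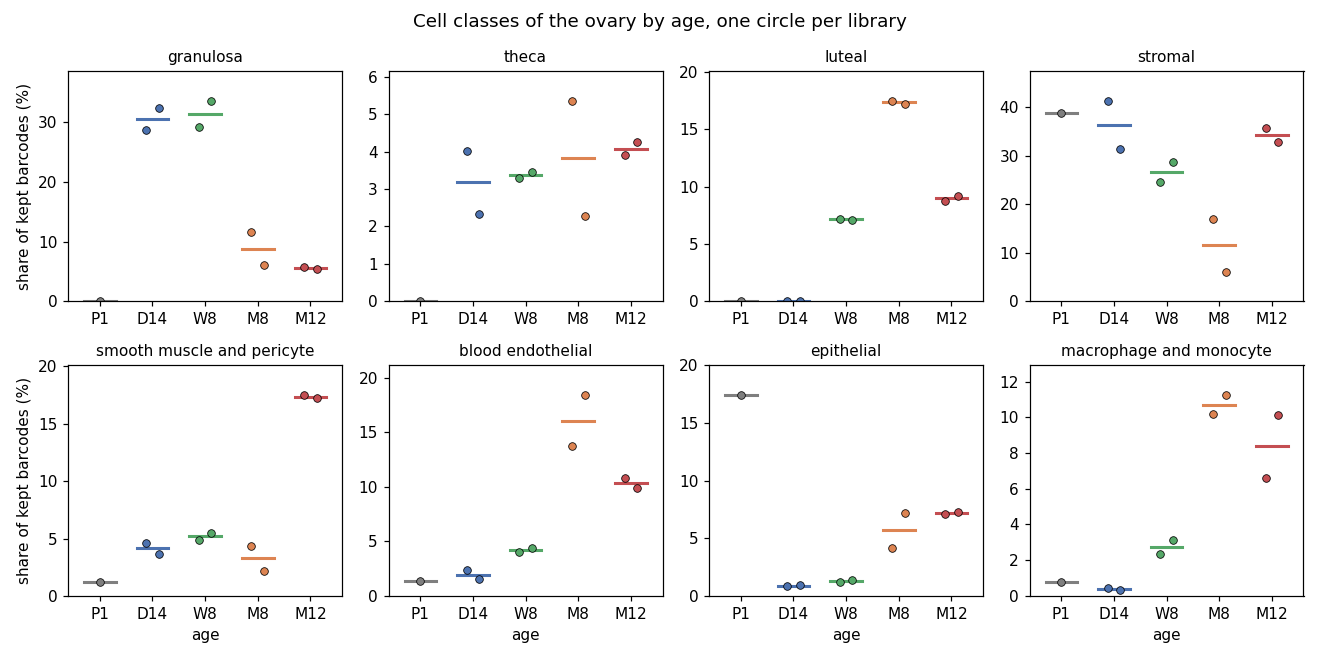
Share of kept barcodes (percent) of 8 cell classes at the 5 ages, with a circle per library and a bar at the mean. Granulosa cells fell from a mean of 31.3% at W8 to 5.57% at M12, while epithelial cells went from 1.26% to 7.17%.

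Comparing W8 with D14 asks how the prepubertal ovary differs from the cycling young adult ovary. Luteal cells, the progesterone-producing cells that form after ovulation, were 1 and 0 barcodes at D14, which allows up to 0.0441% and 0.0343%. They were 7.15% ± 0.0645 (SD, n = 2 libraries) of barcodes at W8 (adjusted p = 1.38e-15). Macrophages and monocytes rose from 0.389% ± 0.0766 to 2.74% ± 0.568 (log2 2.81 ± 0.54, adjusted p = 8.63e-06). Dendritic cells rose by log2 4.76 ± 0.73, adjusted p = 1.03e-07, and T, NK and innate lymphoid cells by log2 2.39 ± 0.55, adjusted p = 0.000188. Barcodes called erythroid rose from 2 and 0 to 92 and 33 (adjusted p = 1.89e-08). Granulosa cells were 30.4% ± 2.52 at D14 and 31.3% ± 3.08 at W8 (log2 0.04 ± 0.48, adjusted p = 0.934). Stromal cells were 36.3% ± 7.07 and 26.6% ± 2.85 (log2 -0.45 ± 0.48, adjusted p = 0.498), and blood endothelial cells 1.96% ± 0.647 and 4.2% ± 0.228 (log2 1.09 ± 0.49, adjusted p = 0.0712). In all, 5 of 14 classes passed. Without D14 replicate 2 the count was 3, with the erythroid and dendritic calls lost (adjusted p = 0.0699 and 0.0525). With centred log ratios it was 11, with the macrophage and T cell calls lost (adjusted p = 0.129 and 0.449). It was 10 without low-UMI clusters, and the erythroid call was lost at clustering resolution 2 (adjusted p = 0.494).

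Genes of interferon response, antigen presentation, steroid hormone synthesis, inflammatory signalling and oxidative phosphorylation were called up between D14 and W8 in each of the 5 classes tested. These lists had adjusted p = 0.12 to 0.443 with an estimated correlation. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), a chain of the MHC class II molecule, rose in macrophages and monocytes (3828 ± 318 against 34.2 ± 16.9 CPM, 117-fold higher, log2 6.87 ± 0.24, adjusted p = 8.76e-08). The D14 macrophages were only 56 and 36 cells. In endothelial cells the MHC class I gene H2-D1 rose (1644 ± 1.98 against 442 ± 93 CPM, 3.72-fold higher, log2 1.90 ± 0.14, adjusted p = 3.12e-05). Theca cells, which supply androgen to the follicle, rose in Cyp11a1 (ENSMUSG00000032323, chromosome 9, 58006411 to 58027023). This enzyme of the first step of steroid synthesis was at 8106 ± 135 against 2562 ± 67.2 CPM, 3.16-fold higher, log2 1.66 ± 0.05, adjusted p = 1.49e-13.

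**Figure D2:**
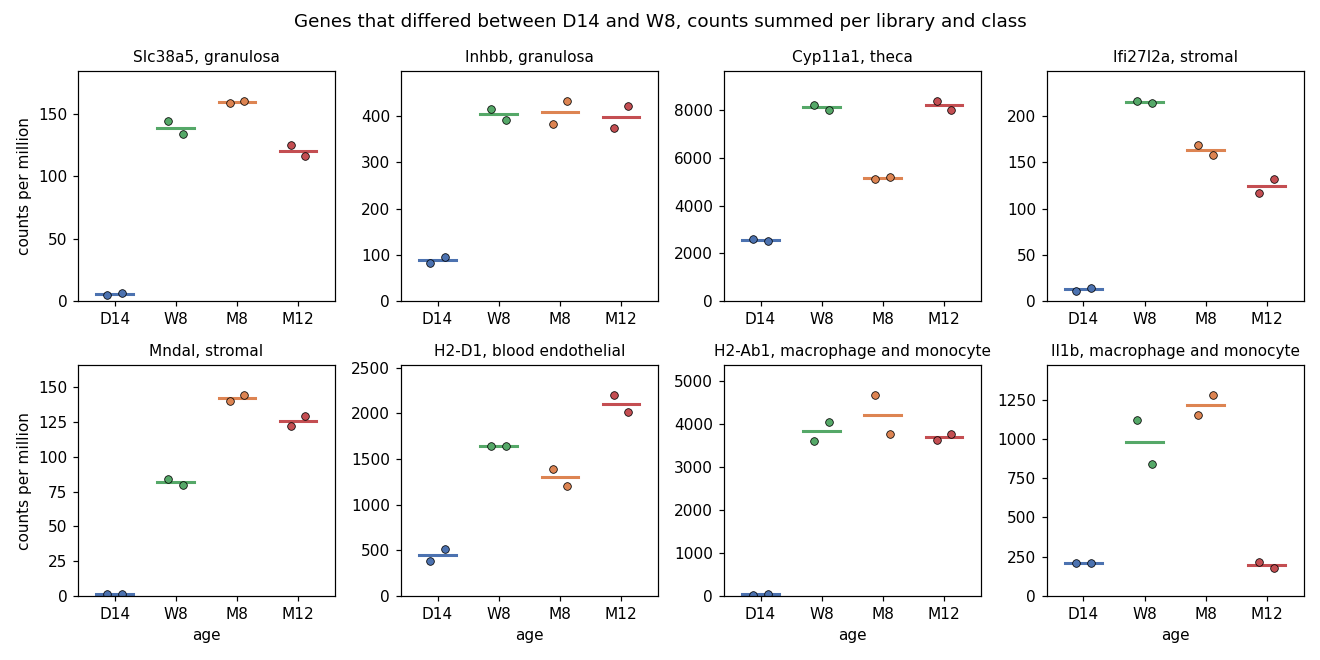
Levels of 8 genes in named cell classes (CPM, linear axis) at D14, W8, M8 and M12, with a circle per library and a bar at the mean. H2-Ab1 in macrophages and monocytes has a mean of 34.2 CPM at D14 and 3828 CPM at W8, and Slc38a5 in granulosa cells 5.62 and 139 CPM.

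In granulosa cells, Slc38a5 (ENSMUSG00000031170, chromosome X, 8271133 to 8280179), an amino acid transporter, rose (139 ± 7.57 against 5.62 ± 1.09 CPM, 24.7-fold higher, log2 4.63 ± 0.10, adjusted p = 3.58e-11). Crabp2, which carries retinoic acid, also rose (73.5 ± 9.09 against 3.72 ± 0.109 CPM, 19.8-fold higher, log2 4.31 ± 0.11, adjusted p = 1.33e-11). Hspa1b, a heat shock gene with the near-identical copy Hspa1a, rose 36.5-fold (log2 5.19 ± 0.68, adjusted p = 0.00545). The lowest log2 changes were of oocyte genes, Padi6 (log2 -4.69 ± 0.47), Zp3 (log2 -4.58 ± 0.43) and H1foo (log2 -4.58 ± 0.75). The Zp3 call was lost without W8 replicate 1. That of H1foo was lost without W8 or M8 replicate 1 or 2. It was also lost without both M8 libraries or after thinning (adjusted p = 0.0674 to 0.121). The transforming growth factor beta family, which holds the inhibins and activins of follicle growth, was called up in granulosa cells. In it, 12 rose, 8 fell and 9 did not pass of 29 measured (12 and 8 adjusted over the list alone). The median was log2 0.21, or 0.49 after thinning to equal depth, with adjusted p = 0.179 with an estimated correlation. Its members Inhbb (log2 2.18 ± 0.09, adjusted p = 2.32e-08), Ltbp1 (log2 1.12 ± 0.07), Fst (log2 0.87 ± 0.07) and Bmpr2 (log2 0.45 ± 0.05) rose. In all, 6280 of 15438 genes tested passed, 2873 higher and 3407 lower (686 and 922 by at least 2-fold). The count was 2770 after thinning and 3658 without W8 replicate 1. D14 granulosa cells lay in clusters 33 and 16 and W8 cells in 21 and 10, with the cycling cluster 26 shared. Cluster 10, with Slc38a5, Crabp2 and Inhbb among its top genes, held 20 and 2 cells at D14 and 776 and 817 at W8. Their rise may come from this mix, and no test was run within a shared cluster.

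Theca cells rose in Abcb1b, an efflux pump (342 ± 75 against 4.16 ± 1.87 CPM, 76.2-fold higher, log2 6.25 ± 0.34, adjusted p = 0.000294), and in S100a6 (log2 5.07 ± 0.29, adjusted p = 0.000236). Both are also top genes of luteal clusters (7 and 13), a class D14 all but lacks, so luteal RNA may add to their rise. Lgals3 had 766 counts at W8 and 1 at D14, a ratio of 871 (counting interval 156 to 34460). Cd24a fell (11.1 ± 4.23 against 78.3 ± 5.39 CPM, 7.0-fold lower, log2 -2.81 ± 0.17, adjusted p = 2.05e-07). The oocyte genes Zp3 (log2 -4.31 ± 0.41) and Ooep (log2 -3.55 ± 0.52) fell too, the call of Ooep being lost without W8 replicate 1 or 2. At resolution 2, theca cells of D14 lay in cluster 34 (509 and 259 cells, W8 0 and 4) and those of W8 in 48 (412 and 396, D14 9 and 0). Of the theca genes, 3700 of 12438 passed, 1936 higher and 1764 lower. That count was 2005 with DESeq2 and 2382 without W8 replicate 1. In stromal cells, the interferon-inducible genes Mndal (ENSMUSG00000090272, chromosome 1, 173849126 to 173942491) and Ifi203 (ENSMUSG00000039997, chromosome 1, 173920407 to 173942672) rose. Mndal went from 1.24 to 81.8 CPM (log2 5.99 ± 0.11, adjusted p = 1.29e-12) and Ifi203 rose by log2 5.96 ± 0.10. These genes overlap on the same strand, so their counts are not separable. Hspa1b rose (log2 4.50 ± 1.09, adjusted p = 0.0342). Its call was lost without D14, W8 or M12 replicate 1 or 2 and at adjusted p = 0.0506 without a count filter. The oocyte genes Nlrp14 (log2 -5.37 ± 0.32, adjusted p = 0.000238), Khdc1b (log2 -5.04 ± 0.84) and Padi6 (log2 -4.78 ± 0.36) fell. The Khdc1b call was lost without W8 or M8 replicate 1 or 2. It was also lost at adjusted p = 0.0503 to 0.0857 without both M8 libraries, after thinning or without a count filter. Of the stromal genes, 6482 of 15174 passed, 3036 higher and 3446 lower, against 4300 without W8 replicate 1. Stromal cells of D14 lay in cluster 30 and those of W8 in 24, 27 and 18.

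In blood endothelial cells, H2-Q6, an MHC class I gene similar in sequence to H2-Q7, rose (65.7 ± 11.5 against 3.46 ± 3.48 CPM, 21.1-fold higher, log2 4.40 ± 0.42, adjusted p = 0.00116). Ifi27l2a, an interferon-inducible gene, rose by log2 3.81 ± 0.48 (adjusted p = 0.0568 without D14 replicate 1). Hspa1b rose by log2 5.21 ± 0.80. Its call was lost without D14, W8 or M12 replicate 1 or 2 and at adjusted p = 0.0509 with a replicate block. The oocyte genes Padi6 (log2 -4.66 ± 0.34), Zp3 (log2 -4.07 ± 0.18) and Gdf9 (log2 -3.99 ± 0.34) fell. Of the endothelial genes, 1352 of 12493 passed, 699 higher and 653 lower. The count moved to 463 without D14 replicate 1, 546 without D14 replicate 2, 390 without W8 replicate 1 and 465 without W8 replicate 2. It was 900 without M12 replicate 1, 892 without M12 replicate 2, 2850 without M8 replicate 1 and 2837 without M8 replicate 2. It was 2766 without both M8 libraries, 2038 without a count filter and 2463 without low-UMI clusters.

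Macrophages and monocytes rose in Ear2, a ribonuclease of myeloid cells, which had 308 counts at W8 and 0 at D14. This is at least 18.8-fold higher, against 3 counts over the group. Chil3, a chitinase-like protein, had 233 counts against 0, at least 14.2-fold higher. The Chil3 call was lost at adjusted p = 0.0813 to 0.143 without D14 replicate 1 or 2 and 0.0754 to 0.301 with at least 1000 genes, with a replicate block or without low-UMI clusters. H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674), another MHC class II chain, rose (3197 ± 84.4 against 13 ± 10.6 CPM, 267-fold higher, log2 8.06 ± 0.30, adjusted p = 1.47e-07). D14 levels of this class rest on 56 and 36 cells, whose red cell RNA was at 33.9 and 10692 CPM. The oocyte genes Padi6 (log2 -4.29 ± 0.60), Khdc1b and Dppa5a fell. The call of Khdc1b was lost without D14 replicate 1 or 2 and that of Dppa5a without D14 replicate 2. Of the macrophage genes, 857 of 11979 passed, 548 higher and 309 lower. This count was 410 without D14 replicate 1, 358 without D14 replicate 2, 441 without W8 replicate 1 and 388 without W8 replicate 2. It was 1343 without a count filter and 1338 without low-UMI clusters.

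Interferon response genes, induced by antiviral signalling, were called up in all 5 classes. Their medians ran from log2 0.79 in macrophages to 2.50 in stromal cells. Of 117 gene-class pairs, 82 rose, 0 fell and 35 did not pass (89 and 0 over the list alone). The interferon calls had adjusted p = 0.12 to 0.314 with an estimated correlation. In stromal cells Ifi27l2a rose (215 ± 1.45 against 12.9 ± 2.05 CPM, 16.8-fold higher, log2 4.07 ± 0.10, adjusted p = 1.06e-09), with Ifit3 (log2 4.70 ± 0.15) and Gbp2 (log2 3.05 ± 0.11). Endothelial cells rose in Irf7 (log2 2.09 ± 0.13), Ifi44 (log2 2.23 ± 0.17) and Rtp4 (log2 1.44 ± 0.12). Theca rose in Ifi27 (log2 1.51 ± 0.08) and Xaf1 (log2 2.42 ± 0.21), and granulosa cells in Isg15 (log2 2.33 ± 0.30). Antigen presentation genes were called up in all 5 classes. Of 88 gene-class pairs, 64 rose, 1 fell and 23 did not pass (74 and 1 over the list alone). The antigen presentation calls had adjusted p = 0.12 to 0.331 with an estimated correlation. Among the MHC class I genes, H2-D1 (log2 1.48 ± 0.10) rose in theca, H2-T23 (log2 1.46 ± 0.10) in granulosa and B2m (log2 1.77 ± 0.13) in endothelial cells. The immunoproteasome gene Psmb9 (log2 3.11 ± 0.10) rose in stromal cells. Of the class II genes, Cd74 (log2 5.56 ± 0.22) rose in macrophages and H2-Ab1 (log2 4.52 ± 0.19) in stromal cells. Immune RNA in non-immune classes went from 6.47 to 10.5 CPM at D14 to 49.2 to 87.4 CPM at W8. It was called up in all 5 classes, with 11 of 13 genes up in stromal and 12 of 13 in granulosa cells. Of 60 gene-class pairs, 39 rose, 0 fell and 21 did not pass (42 and 0 over the list alone). The immune RNA calls had adjusted p = 0.143 to 0.492 with an estimated correlation. Its median in endothelial cells was log2 4.05, or 2.86 with genes at 0 set to their bound. In macrophages it was 0.39, or 0.26 at the bound and 0.14 after thinning. Fry, a test of a list's net direction, gave adjusted p = 0.122 for interferon and 0.122 for immune RNA in macrophages, and 0.373 for immune RNA in endothelial cells.

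Inflammatory cytokine and chemokine genes were called up in all 5 classes. Of 110 gene-class pairs, 59 rose, 4 fell and 47 did not pass (63 and 9 over the list alone). The inflammatory calls had adjusted p = 0.186 to 0.363 with an estimated correlation. In stromal cells, the monocyte attractant Ccl2 rose (20.2 ± 1.16 against 0.24 ± 0.0638 CPM, 79.9-fold higher, log2 6.32 ± 0.24, adjusted p = 3.86e-08), with Ccl7 (log2 6.08 ± 0.34) and Ccl11 (log2 4.72 ± 0.29), while Cxcl12 fell (log2 -1.04 ± 0.07). Macrophages rose in the cytokine Il1b (981 ± 194 against 207 ± 0.283 CPM, 4.73-fold higher, log2 2.24 ± 0.17, adjusted p = 2.02e-05), the neutrophil attractant Cxcl1 (log2 3.63 ± 0.31) and Vcam1 (log2 2.92 ± 0.18). Cluster 5, a low-UMI cluster with Il1b among its top genes, held 8 and 4 macrophages at D14 and 116 and 172 at W8. Granulosa cells rose in Ccl4 (log2 5.43 ± 0.34) and Spp1 (log2 4.23 ± 0.34), which macrophages also make, and theca fell in Vcam1 (log2 -1.98 ± 0.19). Medians were log2 1.63 in granulosa, 3.56 in theca, 3.61 in stromal, 1.60 in endothelial cells and 1.57 in macrophages. With genes at 0 at their bound, the last 4 were 3.19, 3.46, 1.55 and 1.49. With fry, the theca and endothelial calls were lost (adjusted p = 0.119 and 0.184). Senescence and secretory genes were called up in stromal cells and macrophages. Of 110 gene-class pairs, 35 rose, 14 fell and 61 did not pass (42 and 17 over the list alone). The senescence calls had adjusted p = 0.186 to 0.314 with an estimated correlation. The growth factor binding protein Igfbp7 (log2 1.01 ± 0.07) and the protease Ctsb (log2 0.49 ± 0.06) rose in stromal cells. In macrophages Ctsb (log2 1.16 ± 0.14) rose and Igfbp4 (log2 -2.13 ± 0.17) fell, and fry gave adjusted p = 0.0685.

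Steroid hormone synthesis genes were called up in all 5 classes. Of 93 gene-class pairs, 47 rose, 5 fell and 41 did not pass (49 and 5 over the list alone). The steroid calls had adjusted p = 0.12 to 0.354 with an estimated correlation. Granulosa cells rose in Cyp11a1 (138 ± 11 against 23.4 ± 2.6 CPM, 5.86-fold higher, log2 2.55 ± 0.09, adjusted p = 2.20e-09), in the cholesterol carrier Star (log2 1.83 ± 0.13) and in Mgarp (log2 3.15 ± 0.09). Theca cells also rose in Mgarp (log2 1.27 ± 0.07), Fdxr (log2 0.65 ± 0.06) and the luteinizing hormone receptor Lhcgr (log2 0.83 ± 0.07). In stromal cells Fdx1 (log2 1.38 ± 0.07) and Star (log2 4.23 ± 0.18) rose. Endothelial cells had 2 steroid genes past the test, Star and Tspo, with median log2 1.06. That median was 0.70 with at least 1000 genes per barcode and 0.51 without low-UMI clusters. The steroid call was lost with fry in endothelial cells and macrophages (adjusted p = 0.218 and 0.169). Beside it, follicle and luteal RNA was called up in 4 classes, with Akr1c18 (log2 2.83 ± 0.18) in stromal cells. Of 63 gene-class pairs, 23 rose, 5 fell and 35 did not pass (26 and 5 over the list alone). The follicle RNA calls had adjusted p = 0.193 to 0.601 with an estimated correlation. In macrophages the follicle RNA call was lost without D14 or M8 replicate 1 or 2 and with fry (adjusted p = 0.558). Its median of 1.44 there was 0.94 with genes at 0 at their bound and 0.94 without low-UMI clusters. Cholesterol synthesis and uptake genes were called up in granulosa, stromal and endothelial cells. Of 112 gene-class pairs, 51 rose, 3 fell and 58 did not pass (54 and 4 over the list alone). The cholesterol calls had adjusted p = 0.143 with an estimated correlation. In granulosa cells Dhcr7 (log2 1.08 ± 0.09) and Cyp51 (log2 0.91 ± 0.07) rose. So did Cyp51 (log2 1.60 ± 0.10) in stromal and Idi1 (log2 1.58 ± 0.17) in endothelial cells.

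Nuclear genes of oxidative phosphorylation were called up in all 5 classes, with medians from log2 0.18 in endothelial cells to 0.37 in macrophages. Of 255 gene-class pairs, 128 rose, 4 fell and 123 did not pass (149 and 5 over the list alone). The respiratory chain calls had adjusted p = 0.186 to 0.443 with an estimated correlation. Examples are Uqcrq (log2 0.75 ± 0.05) and Ndufc1 (log2 0.69 ± 0.06) in granulosa, Atp5h (log2 0.56 ± 0.06) in theca and Atp5g1 (log2 0.95 ± 0.13) in macrophages. The endothelial call was lost with fry (adjusted p = 0.0696). Antioxidant and metallothionein genes were called up in all 5 classes. Of 144 gene-class pairs, 50 rose, 9 fell and 85 did not pass (54 and 12 over the list alone). The antioxidant calls had adjusted p = 0.143 to 0.579 with an estimated correlation. The glutathione peroxidases Gpx3 (log2 1.79 ± 0.07, adjusted p = 1.14e-10) in granulosa and Gpx1 (log2 1.03 ± 0.07) in theca rose, as did the metallothionein Mt1 (log2 1.5 ± 0.09) in stromal cells. In endothelial cells that call was lost without D14 replicate 2 or W8 replicate 1, and at adjusted p = 0.424 with fry. After thinning, the antioxidant median went from 0.06 to 0.12 in endothelial cells and from 0.39 to 0.17 in macrophages. Unfolded protein response genes, mostly chaperones of the endoplasmic reticulum, were called up in granulosa, theca, endothelial cells and macrophages. Of 104 gene-class pairs, 48 rose, 1 fell and 55 did not pass (53 and 1 over the list alone). The chaperone calls had adjusted p = 0.143 to 0.186 with an estimated correlation. Among them, Sdf2l1 (log2 1.26 ± 0.11) rose in theca, Hsp90b1 (log2 0.56 ± 0.05) in granulosa cells and Pdia6 (log2 1.30 ± 0.14) in macrophages. Immediate early and heat shock genes, which also respond to tissue dissociation, were called up in granulosa, endothelial cells and macrophages. Of 135 gene-class pairs, 30 rose, 15 fell and 90 did not pass (38 and 16 over the list alone). The immediate early calls had adjusted p = 0.186 to 0.695 with an estimated correlation. In macrophages Atf3 (log2 1.85 ± 0.15) rose, and in endothelial cells Hspb1 (log2 2.19 ± 0.27) rose and Egr1 (log2 -0.88 ± 0.16) fell. Endothelial cells lost that call at adjusted p = 0.0569 without D14 replicate 2 and 0.0724 without W8 replicate 1, at 0.0518 with replicate number as a block and at 0.409 with fry. Granulosa cells lost it with fry (0.111), and the macrophage median of 0.53 was 0.35 after thinning.

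Cell cycle genes were called up in endothelial cells (5 of 30 rose) and macrophages (0 rose and 0 fell), and down in theca (9 fell). Of 150 gene-class pairs, 19 rose, 17 fell and 114 did not pass (20 and 18 over the list alone). The cell cycle calls had adjusted p = 0.186 to 0.681 with an estimated correlation. Of DNA replication, Pcna (log2 0.84 ± 0.20) and Rrm2 (log2 1.68 ± 0.39) rose in endothelial cells, and the mitotic genes Bub1 (log2 -2.56 ± 0.70) and Cenpf (log2 -0.99 ± 0.27) fell in theca. Fry gave adjusted p = 0.108 in endothelial cells and 0.558 in macrophages. The macrophage call was also lost without D14 replicate 1, W8 replicate 1 or M8 replicate 1 or 2. Its median of 0.48 was 0.05 without low-UMI clusters. Extracellular matrix genes were called down in theca, where 6 rose and 12 fell of 31. Of 155 gene-class pairs, 31 rose, 32 fell and 92 did not pass (31 and 35 over the list alone). The theca matrix genes had adjusted p = 0.375 with an estimated correlation. The matrix proteins Fn1 (log2 -2.0 ± 0.09, adjusted p = 8.06e-11) and Col18a1 (log2 -1.69 ± 0.15) fell there, and the collagen chaperone Serpinh1 (log2 0.66 ± 0.07) rose. The matrix call was lost without D14 replicate 1 or W8 replicate 1 or 2. Cytosolic ribosomal protein genes were called down in theca, stromal and endothelial cells and up in macrophages. Their medians were log2 -0.15, -0.23, -0.19 and 0.10. Of 408 gene-class pairs, 8 rose, 97 fell and 303 did not pass (7 and 97 over the list alone). The ribosomal calls had adjusted p = 0.309 to 0.514 with an estimated correlation. Rpl3 (log2 -0.40 ± 0.05) in theca and Rps14 (log2 -0.49 ± 0.05) in stromal cells fell. Rps27l, a ribosomal protein-like gene induced by p53, rose in theca (log2 0.41 ± 0.07) and macrophages (log2 0.83 ± 0.13). The theca ribosomal median was -0.10 with at most 10% mitochondrial UMIs, and the macrophage median 0.02 after thinning. Fry gave adjusted p = 0.111 and 0.242 in endothelial cells and macrophages. Germ cell RNA was called down in all 5 classes, in theca from 332 CPM at D14 to 26.1 CPM at W8. Of 71 gene-class pairs, 0 rose, 67 fell and 4 did not pass (0 and 69 over the list alone). The germ cell RNA calls had adjusted p = 0.143 to 0.314 with an estimated correlation. Red cell RNA was called up in 3 of 4 classes tested. Of 20 gene-class pairs, 6 rose, 0 fell and 14 did not pass (5 and 0 over the list alone). The red cell RNA calls had adjusted p = 0.243 to 0.434 with an estimated correlation. The endothelial red cell call was lost without D14 replicate 1 or W8 replicate 2, and at adjusted p = 0.349 with fry. Its median was 0.48 without low-UMI clusters against 1.30.

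**Figure D3:**
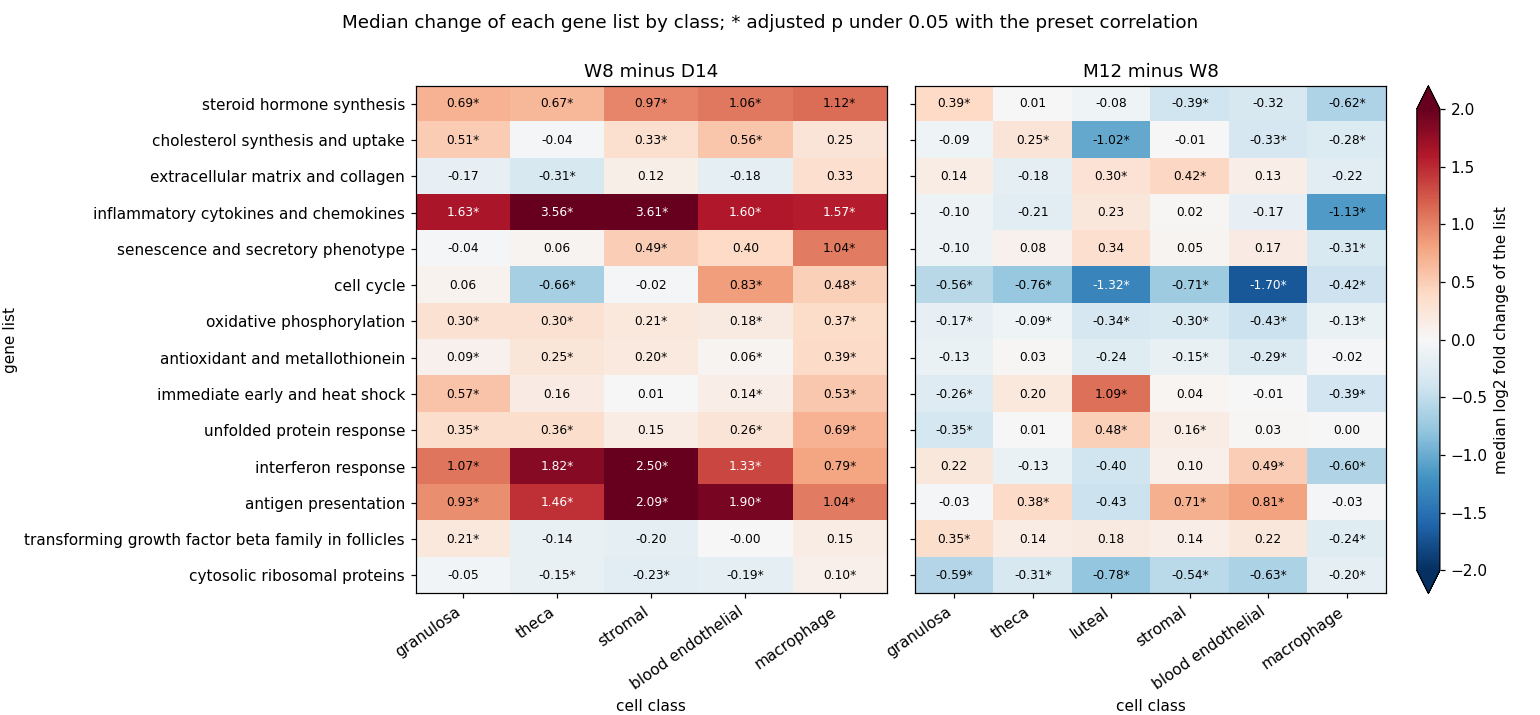
Median log2 change of 14 gene lists (vertical axis) in each cell class (horizontal axis) for W8 against D14 and for M12 against W8, with the colour scale in log2 units and a star where adjusted p is under 0.05 with a preset correlation. Interferon response reaches 2.50 in stromal cells at W8 against D14, and ribosomal protein genes reach -0.78 in luteal cells at M12 against W8.

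Comparing M12 with W8 asks how the ageing ovary differs from the young adult ovary. Granulosa cells fell from 31.3% ± 3.08 to 5.57% ± 0.263 of barcodes (log2 -2.49 ± 0.51, adjusted p = 4.78e-05). Epithelial cells rose from 1.26% ± 0.144 to 7.17% ± 0.114 (log2 2.50 ± 0.52, adjusted p = 4.78e-05), and smooth muscle cells and pericytes from 5.18% ± 0.466 to 17.4% ± 0.158 (log2 1.75 ± 0.5, adjusted p = 0.00246). Macrophages and monocytes rose from 2.74% ± 0.568 to 8.38% ± 2.5 (log2 1.61 ± 0.5, adjusted p = 0.00461), and blood endothelial cells from 4.2% ± 0.228 to 10.3% ± 0.651 (log2 1.30 ± 0.49, adjusted p = 0.0212). Neutrophils and mast cells rose by log2 3.01 ± 0.76, adjusted p = 0.000797. Erythroid cells, 0.574% ± 0.352 at W8, were at 0 at M12 (adjusted p = 5.83e-08). Luteal cells were 7.15% ± 0.0645 and 8.97% ± 0.306 (log2 0.33 ± 0.48, adjusted p = 0.576), and stromal cells 26.6% ± 2.85 and 34.2% ± 2.01. In all, 7 of 14 classes passed, against 4 with TMM scaling, 4 without W8 replicate 1 and 4 without M12 replicate 2. The granulosa and epithelial calls were kept in every alternative. Smooth muscle lost its call with TMM (adjusted p = 0.099) and without W8 replicate 1 (0.0813). Macrophages lost theirs with TMM (0.175), without W8 replicate 1 (0.134) and without M12 replicate 2 (0.0919). Endothelial cells lost theirs with centred log ratios (0.0501) and TMM (0.287). The endothelial value was also 0.18 without W8 replicate 1, 0.134 without W8 replicate 2, 0.104 without M12 replicate 1 and 0.0902 without M12 replicate 2. Neutrophils and mast cells were at 0.0652 without D14 replicate 1, 0.0652 without D14 replicate 2 and 0.0919 without M12 replicate 2.

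Within the classes, ribosomal protein, oxidative phosphorylation and cell cycle genes were called down in all 6 classes between W8 and M12. These lists had adjusted p = 0.374 to 0.708 with an estimated correlation. Stromal cells rose in collagen genes such as Col1a1 (2193 ± 55.2 against 1258 ± 15.9 CPM, 1.74-fold higher, log2 0.80 ± 0.05, adjusted p = 1.02e-06). They also rose in the complement gene C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136), at 61.5 ± 4.52 against 4.74 ± 0.262 CPM, 12.9-fold higher, log2 3.69 ± 0.31, adjusted p = 0.000678. Granulosa cells rose in Lhcgr (ENSMUSG00000024107, chromosome 17, 88716481 to 88791990), the receptor of luteinizing hormone (52.3 ± 1.43 against 11.5 ± 0.15 CPM, 4.53-fold higher, log2 2.18 ± 0.11, adjusted p = 1.41e-08).

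**Figure D4:**
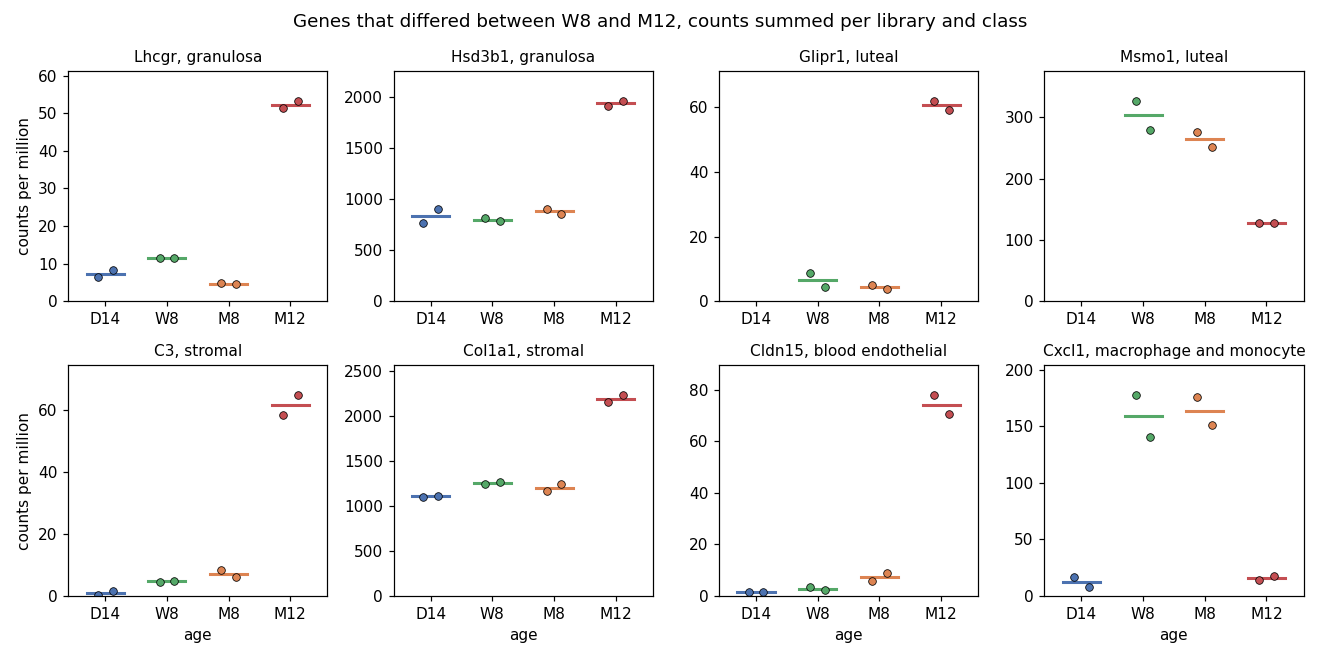
Levels of 8 genes in named cell classes (CPM, linear axis) at D14, W8, M8 and M12, with a circle per library and a bar at the mean. C3 in stromal cells has a mean of 4.74 CPM at W8 and 61.5 CPM at M12, and Cxcl1 in macrophages and monocytes 159 and 16.1 CPM.

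In granulosa cells, the prolactin receptor Prlr rose beside Lhcgr (141 ± 18.1 against 31.1 ± 1.78 CPM, 4.55-fold higher, log2 2.19 ± 0.11, adjusted p = 8.48e-07), both also markers of luteal cells. Rhox8, a homeobox gene, rose (log2 2.38 ± 0.30, adjusted p = 0.00612). In cluster 21, the best filled at both ages, Rhox8 was at log2 -1.08 (adjusted p = 0.000606). Steroid hormone synthesis genes were called up, with adjusted p = 0.374 with an estimated correlation. In this list, 11 rose, 0 fell and 9 did not pass of 20 measured (12 and 0 adjusted over the list alone). The rise included Hsd3b1 (log2 1.28 ± 0.07, adjusted p = 1.83e-08), which makes progesterone, and Star (log2 1.18 ± 0.13). The list's median of log2 0.39 was -0.02 within cluster 21. Cyp11a1 rose by log2 1.0 ± 0.08 in the class, but was at -0.32 (adjusted p = 0.00875) within cluster 21, and its call was lost at resolution 2 (0.252). The transforming growth factor beta family was called up, with adjusted p = 0.374 with an estimated correlation. Here 12 rose, 3 fell and 14 did not pass of 29 measured (14 and 3 adjusted over the list alone), with the receptor genes Bmpr2 (log2 0.75 ± 0.06), Tgfbr1 (log2 0.88 ± 0.07) and Bmpr1b (log2 0.68 ± 0.06) up. Unfolded protein response genes were called down (1 rose, 13 fell and 7 did not pass of 21 measured), with Pdia6 (log2 -0.67 ± 0.06) and Hspa5 (log2 -0.47 ± 0.06). Immediate early and heat shock genes were also called down (1 rose, 6 fell and 20 did not pass of 27 measured), with Hspa8 (log2 -0.39 ± 0.05). These lists had adjusted p = 0.42 and 0.677 with an estimated correlation. The immediate early median of -0.26 was -0.08 within cluster 21, and fry gave adjusted p = 0.47. Follicle and luteal RNA was called up (5 rose, 3 fell and 5 did not pass of 13 measured), with adjusted p = 0.54 with an estimated correlation and 0.0789 without W8 replicate 2. Its median of 0.37 was -0.20 within cluster 21. Of the granulosa genes, 4695 of 15438 passed, 2219 higher and 2476 lower, against 2987 without W8 replicate 1. Cluster 21 held 2032 and 2108 cells at W8 and 232 and 203 at M12. Cluster 10, with Inhba and Slc38a5, held 776 and 817 cells at W8 and 171 and 147 at M12.

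Luteal cells rose in Glipr1 (ENSMUSG00000056888, chromosome 10, 111985448 to 112002631), a protein of the CAP family (60.6 ± 1.98 against 6.51 ± 3.08 CPM, 9.31-fold higher, log2 3.22 ± 0.27, adjusted p = 0.000406). The olfactory receptor gene Olfr810 rose (log2 3.11 ± 0.28, adjusted p = 0.000578), and the matrix protein Tnc rose 8.65-fold (log2 3.11 ± 0.42, adjusted p = 0.00926). The Tnc call was lost at adjusted p = 0.0504 without M12 replicate 2. Cholesterol synthesis and uptake genes were called down, with adjusted p = 0.54 with an estimated correlation. Of this list, 0 rose, 20 fell and 3 did not pass of 23 measured (0 and 20 adjusted over the list alone), with median log2 -1.02. The sterol enzyme Msmo1 fell (129 ± 0.0283 against 303 ± 33.7 CPM, 2.36-fold lower, log2 -1.24 ± 0.09, adjusted p = 1.86e-06), with Insig1 (log2 -1.71 ± 0.12) and Nsdhl (log2 -1.15 ± 0.12). Immediate early and heat shock genes were called up (14 rose, 2 fell and 11 did not pass of 27 measured), with Fosb (log2 2.13 ± 0.12, adjusted p = 4.84e-06) and Egr1 (log2 1.24 ± 0.10). Unfolded protein response genes were also called up (17 rose, 3 fell and 2 did not pass of 22 measured), with Xbp1 (log2 1.08 ± 0.09) and Hspa5 (log2 0.70 ± 0.08) up and Asns (log2 -1.32 ± 0.14) down. These lists had adjusted p = 0.597 and 0.42 with an estimated correlation. Matrix genes were called up (9 rose, 2 fell and 21 did not pass of 32 measured), with adjusted p = 0.709 with an estimated correlation. Among them, the protease inhibitors Timp1 (log2 1.70 ± 0.10) and Timp3 (log2 1.23 ± 0.07) rose. The matrix call was lost at adjusted p = 0.109 without W8 replicate 2 and 0.059 without M12 replicate 1. Fry gave 0.159 for matrix and 0.0546 for immediate early genes. Of the luteal genes, 6681 of 13666 passed, 3355 higher and 3326 lower. The count was 3772 in cluster 13 alone, which holds 289 and 297 cells at W8 and 635 and 617 at M12. Cluster 36, with 369 and 386 cells at W8, had 0 and 1 at M12. Within cluster 13 the medians of matrix, immediate early and unfolded protein response genes were log2 0.15, 0.53 and 0.16. In the class they were 0.30, 1.09 and 0.48.

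Stromal cells rose in C3 and in the matrix gene Efemp1 (89.6 ± 0.566 against 22.7 ± 0.781 CPM, 3.95-fold higher, log2 1.98 ± 0.23, adjusted p = 0.00234). The glutamate receptor gene Grin2b rose by log2 1.84 ± 0.33 (adjusted p = 0.0589 to 0.0733 without W8 replicate 1 or M12 replicate 1 or 2). Extracellular matrix and collagen genes were called up, with adjusted p = 0.362 with an estimated correlation. Here 22 rose, 1 fell and 9 did not pass of 32 measured (23 and 1 adjusted over the list alone), with median log2 0.42, or 0.28 within cluster 24. Examples beside Col1a1 are Col3a1 (log2 0.68 ± 0.05), Tnc (log2 0.91 ± 0.07) and Col6a3 (log2 0.65 ± 0.06). Antigen presentation genes were called up in stromal, endothelial and theca cells. Of 105 gene-class pairs, 32 rose, 3 fell and 70 did not pass (38 and 3 over the list alone). The M12 antigen presentation calls had adjusted p = 0.374 to 0.502 with an estimated correlation. Tapbp (log2 0.88 ± 0.08) and H2-Ab1 (log2 1.10 ± 0.12) rose in stromal, H2-T23 (log2 0.73 ± 0.13) in endothelial and H2-K1 (log2 0.47 ± 0.08) in theca cells. Immune RNA was called in no class, with 11 of 74 gene and class pairs up. Steroid hormone synthesis genes were called down in stromal cells (4 rose, 11 fell and 5 did not pass of 20 measured), with adjusted p = 0.42 with an estimated correlation. Of these, Fdx1 (log2 -0.75 ± 0.07) and Nr5a2 (log2 -1.77 ± 0.21) fell and Akr1c18 (log2 1.63 ± 0.13), a luteal marker, rose. Follicle and luteal RNA was called down in the class (2 rose, 7 fell and 4 did not pass of 13 measured), with adjusted p = 0.54 with an estimated correlation. The granulosa markers Amh (log2 -3.53 ± 0.15) and Inha (log2 -2.52 ± 0.24) fell. The unfolded protein response list was called up (8 rose, 2 fell and 11 did not pass of 21 measured), with Hyou1 (log2 0.91 ± 0.07), and the antioxidant list down (5 rose, 13 fell and 11 did not pass of 29 measured). Of the latter, Prdx2 (log2 -0.56 ± 0.06) fell and Gpx3 (log2 1.17 ± 0.06) rose. These lists had adjusted p = 0.42 and 0.562 with an estimated correlation, and were lost at 0.0601 without M12 replicate 1 and 0.0692 without W8 replicate 1. Of the stromal genes, 6110 of 15174 passed, 3172 higher and 2938 lower, against 3851 without W8 replicate 1 and 3948 without M12 replicate 2. Stromal cells lay mainly in cluster 24 at M12 (1710 and 1490 cells) and in 24, 27 and 18 at W8.

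Blood endothelial cells rose in Cldn15 (ENSMUSG00000001739, chromosome 5, 136966616 to 136975858), a tight junction protein (74.3 ± 5.11 against 2.83 ± 0.917 CPM, 26.4-fold higher, log2 4.72 ± 0.25, adjusted p = 7.67e-07). The fatty acid carrier Fabp4 rose 129-fold (log2 7.01 ± 0.51, adjusted p = 0.00117) and the phosphatase Ptpru by log2 5.05 ± 0.23, adjusted p = 3.69e-07. In the shared cluster 1 their calls were lost (adjusted p = 0.097 and 0.142). The histone gene Hist1h1b fell (log2 -2.58 ± 0.23, adjusted p = 0.000687), as did Cxcl1 (log2 -2.71 ± 0.38, adjusted p = 0.0594 without M12 replicate 2). Granulosa RNA, Inha (log2 -2.81 ± 0.68), fell too. The Inha call was lost at adjusted p = 0.0689 to 0.212 without D14 replicate 1 or 2, W8 replicate 1 or 2 or M12 replicate 1 or 2 and 0.0535 to 0.089 with at most 10% mitochondrial UMIs, with a replicate block, after thinning or without a count filter. Interferon response genes were called up, with adjusted p = 0.374 with an estimated correlation. Of the list, 13 rose, 0 fell and 11 did not pass of 24 measured (17 and 1 adjusted over the list alone), with Ifi44 (log2 0.97 ± 0.14) and Zbp1 (log2 2.23 ± 0.34) up. The list's median of log2 0.49 was -0.05 within cluster 1. There Rsad2, up by log2 2.94 ± 0.13 in the class, was at -0.031 (adjusted p = 0.908), and Irf7, up by log2 0.75 ± 0.10, was at -0.34 (0.0616). Cluster 37, whose top genes are Plvap, Fabp4, Gpihbp1 and Rsad2, held 18 and 17 cells at W8 and 466 and 380 at M12. Cluster 1 held 365 and 380, then 328 and 293. Cholesterol genes were called down (0 rose, 6 fell and 16 did not pass of 22 measured), with Pmvk (log2 -0.70 ± 0.11) and Idi1 (log2 -0.52 ± 0.14). Their median of -0.33 was -0.21 within cluster 1. Antioxidant genes were called down (2 rose, 8 fell and 19 did not pass of 29 measured), with Prdx3 (log2 -0.94 ± 0.12). Follicle and luteal RNA was called down as well (0 rose, 4 fell and 9 did not pass of 13 measured). These 3 lists had adjusted p = 0.42, 0.625 and 0.709 with an estimated correlation. The antioxidant call was lost with fry (0.233), and the follicle RNA call with fry (0.432) and at 0.0877 without W8 replicate 1 and 0.0601 without M12 replicate 1. Of the endothelial genes, 2963 of 12493 passed, 1481 higher and 1482 lower. The count was 752 without W8 replicate 1, 1274 without W8 replicate 2, 1194 without M12 replicate 1 and 720 without M12 replicate 2. It was 4710 without M8 replicate 1 and 4669 without M8 replicate 2, 4642 without both M8 libraries and 1904 with DESeq2.

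Theca cells rose in Nupr1, a stress-response gene (log2 2.08 ± 0.18, adjusted p = 0.000397), a call lost at adjusted p = 0.127 at resolution 2. They fell in the interferon-inducible gene Ifitm1 (29.5 ± 10.8 against 91.8 ± 9.5 CPM, 3.11-fold lower, log2 -1.64 ± 0.21, adjusted p = 0.00531). Tnc was 12.3-fold higher (log2 3.62 ± 0.52, adjusted p = 0.0178). Its call was lost without W8 or M12 replicate 1 or 2 and at adjusted p = 0.102 with at most 10% mitochondrial UMIs. Nupr1 and Tnc are also top genes of luteal cluster 11 at resolution 2, so luteal RNA may add to their rise. The luteal marker Ptgfr was higher by log2 2.36 ± 0.40, lost without W8 or M12 replicate 1 or 2. It was also lost at adjusted p = 0.0534 to 0.0919 with a replicate block or with at most 10% mitochondrial UMIs. Ass1, of arginine synthesis, was at log2 -1.65 ± 0.30, lost at adjusted p = 0.0693 to 0.146 without D14 replicate 1 or 2, W8 replicate 1 or 2 or M12 replicate 1 or 2 and 0.0523 to 0.0805 at resolution 2, without a count filter, with a replicate block or with at most 10% mitochondrial UMIs. Cholesterol synthesis genes were called up, with adjusted p = 0.484 with an estimated correlation and 0.0501 with fry. Of these genes, 8 rose, 0 fell and 14 did not pass of 22 measured (13 and 1 adjusted over the list alone), with the enzymes Hmgcs1 (log2 0.76 ± 0.08, adjusted p = 6.48e-06) and Sqle (log2 0.46 ± 0.11) up. Of the theca genes, 1865 of 12438 passed, 798 higher and 1067 lower. The count was 849 without W8 replicate 1, 1111 without W8 replicate 2, 1225 without M12 replicate 1 and 818 without M12 replicate 2. It was 768 with DESeq2 and 1122 with at most 10% mitochondrial UMIs.

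Macrophages and monocytes fell in the neutrophil attractant Cxcl1 (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), which was at 16.1 ± 2.63 against 159 ± 26.1 CPM, 9.86-fold lower, log2 -3.30 ± 0.19, adjusted p = 1.54e-05. Ptgs2, the inducible cyclooxygenase, fell (13.3 ± 0.185 against 112 ± 26 CPM, 8.36-fold lower, log2 -3.06 ± 0.19, adjusted p = 1.73e-05), and Hspa1b fell (log2 -2.76 ± 0.32, adjusted p = 0.0613 without D14 replicate 1). Inflammatory genes were called down, with adjusted p = 0.374 with an estimated correlation. Of them, 0 rose, 10 fell and 15 did not pass of 25 measured (0 and 14 adjusted over the list alone), with median log2 -1.13. Il1b fell (195 ± 27.9 against 981 ± 194 CPM, 5.04-fold lower, log2 -2.33 ± 0.16, adjusted p = 3.34e-05), as did Ccl3 (log2 -1.44 ± 0.15). Cluster 5 held 116 and 172 cells at W8 and 46 and 313 at M12, and cluster 6 held 145 and 147, then 455 and 405. Gdf3, a growth factor of the TGF-beta family, rose (log2 1.42 ± 0.15, adjusted p = 0.00212), a call lost at adjusted p = 0.0571 without W8 replicate 1. The coagulation factor gene F7 was higher by log2 1.73. Its call was lost without D14 or W8 replicate 1 or 2 and at adjusted p = 0.0933 after thinning. The kinase Fgr was higher by log2 1.52, lost at adjusted p = 0.0752 to 0.347 without D14 replicate 1 or 2 or W8 replicate 1 or 2 and 0.0522 to 0.0781 at resolution 2 or after thinning. Immediate early and heat shock genes were called down (0 rose, 3 fell and 24 did not pass of 27 measured), as were interferon response genes (0 rose, 2 fell and 23 did not pass of 25 measured) and senescence genes (0 rose, 3 fell and 20 did not pass of 23 measured). With these 3 lists at adjusted p = 0.374, 0.42 and 0.374 with an estimated correlation, Fosb (log2 -0.82 ± 0.15) fell. Of the macrophage genes, 85 of 11979 passed, 14 higher and 71 lower. The count was 18 without W8 replicate 1, 30 without W8 replicate 2, 41 without D14 replicate 1 and 44 without D14 replicate 2. It was 351 without M8 replicate 1, 341 without M8 replicate 2 and 298 without M12 replicate 2. It was 410 without both M8 libraries, 332 within cluster 6 and 332 without low-UMI clusters. With DESeq2 it was 225, without a count filter 660, after thinning 45, with doublets kept 198, at resolution 2 54 and with a replicate block 301.

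Some lists were called down in macrophages with no member past the test. Beside red cell and follicle RNA, they are steroid and cholesterol synthesis, the transforming growth factor beta family, cell cycle, oxidative phosphorylation and ribosomal genes. Their medians were log2 -0.62, -0.28, -0.24, -0.42, -0.13 and -0.20. Adjusted p was 0.567, 0.597, 0.597, 0.597, 0.597 and 0.54 with an estimated correlation. With fry it was 0.272, 0.269, 0.286, 0.272, 0.159 and 0.105, with interferon at 0.0631. Cholesterol synthesis was lost without W8 or M12 replicate 1, and cell cycle without M12 replicate 2. Oxidative phosphorylation was lost without W8 replicate 2 and the growth factor family without M12 replicate 1. Within cluster 6, which leaves out the low-UMI cluster 5, the medians of steroid, cholesterol and growth factor genes were -0.33, -0.07 and -0.37. Those of cell cycle and ribosomal genes were 0.005 and -0.13. After thinning, the cell cycle and growth factor medians were -0.66 and -0.87. The steroid median was -0.20 with at least 1000 genes per barcode.

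Ribosomal protein genes were called down in all 6 classes. Medians ran from log2 -0.78 in luteal cells to -0.20 in macrophages. Of 489 gene-class pairs, 0 rose, 339 fell and 150 did not pass (0 and 349 over the list alone). The M12 ribosomal calls had adjusted p = 0.374 to 0.54 with an estimated correlation. Rpsa fell in granulosa (2307 ± 41.1 against 4157 ± 161 CPM, 1.8-fold lower, log2 -0.85 ± 0.05, adjusted p = 1.48e-08), Rps19 (log2 -1.22 ± 0.07) in luteal and Rpl18 (log2 -0.77 ± 0.05) in stromal cells. So did Rplp0 (log2 -0.98 ± 0.13) in endothelial and Rps4x (log2 -0.53 ± 0.05) in theca cells. The luteal median was -0.49 within cluster 13. Oxidative phosphorylation genes were called down in all 6 classes. Of 306 gene-class pairs, 1 rose, 155 fell and 150 did not pass (3 and 174 over the list alone). The M12 respiratory chain calls had adjusted p = 0.381 to 0.597 with an estimated correlation. The subunits Sdhb (log2 -1.05 ± 0.07) in luteal, Atp5g1 (log2 -0.75 ± 0.10) in endothelial, Atp5d (log2 -0.66 ± 0.05) in stromal and Atp5g2 (log2 -0.54 ± 0.05) in granulosa cells fell. The granulosa median of -0.17 was -0.07 within cluster 21. The theca median of -0.09 was -0.06 with at most 10% mitochondrial UMIs, and fry gave adjusted p = 0.129 there. Cell cycle genes were called down in all 6 classes. Of 180 gene-class pairs, 0 rose, 88 fell and 92 did not pass (1 and 106 over the list alone). The M12 cell cycle calls had adjusted p = 0.374 to 0.708 with an estimated correlation. In granulosa cells Tyms (log2 -0.85 ± 0.09) and Cdc20 (log2 -0.64 ± 0.07) fell, with Aurka (log2 -2.11 ± 0.33) in endothelial, Top2a (log2 -1.24 ± 0.12) in stromal and Cdk1 (log2 -1.74 ± 0.25) in theca cells. The granulosa cell cycle median of -0.56 was -0.33 with at most 10% mitochondrial UMIs. The luteal median of -1.32 was -0.74 within cluster 13, and the stromal median of -0.71 was -1.17 within cluster 24. Fry gave adjusted p = 0.0539 in granulosa and 0.278 in luteal cells.

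Germ cell RNA was called down in all 6 classes between W8 and M12, though its summed level in luteal cells went from 389 to 617 CPM. Of 77 gene-class pairs, 1 rose, 25 fell and 51 did not pass (1 and 33 over the list alone). The M12 germ cell RNA calls had adjusted p = 0.374 to 0.772 with an estimated correlation. Its medians ran from -6.05 in macrophages to -3.39 in stromal cells, or from -3.94 to -1.02 over the classes with genes at 0 at their bound. Uchl1, a ubiquitin hydrolase also found in other cells, rose in luteal cells (log2 0.66 ± 0.07, adjusted p = 0.0819 in the shared cluster). In granulosa cells the germ cell call was lost without W8, M8 or M12 replicate 1 or 2. Fry gave adjusted p = 0.568, 0.321, 0.327 and 0.0546 in granulosa, theca, stromal and endothelial cells. Red cell RNA was called down in 4 of 5 classes tested, in stromal cells from 1734 and 1130 CPM at W8 to 9.63 and 6.05 CPM at M12. Of 25 gene-class pairs, 0 rose, 14 fell and 11 did not pass (0 and 19 over the list alone). The M12 red cell RNA calls had adjusted p = 0.566 to 0.622 with an estimated correlation. The globin genes of that list had the lowest log2 changes in granulosa, theca, luteal and stromal cells. Hbb-bt was at log2 -7.82 ± 1.23 in granulosa, lost at adjusted p = 0.0914 to 0.0964 without M12 replicate 1 or 2 and 0.0854 to 0.0957 with doublets kept or at resolution 2. It was at log2 -7.85 ± 1.45 in stromal cells, lost at adjusted p = 0.0662 to 0.11 without W8 replicate 1 or M12 replicate 1 or 2. The red cell call was lost with fry in granulosa, stromal, endothelial cells and macrophages (adjusted p = 0.167, 0.149, 0.269 and 0.454). It was also lost in endothelial cells at 0.0892 without M12 replicate 1 and in macrophages at 0.084 without M12 replicate 2. Follicle RNA was called down in macrophages (0 of 12 genes passed, median log2 -1.38, or -2.66 within cluster 6, fry adjusted p = 0.206). Of 76 gene-class pairs, 10 rose, 21 fell and 45 did not pass (11 and 23 over the list alone). The M12 follicle RNA calls had adjusted p = 0.519 to 0.709 with an estimated correlation.

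The M8 libraries split the ageing interval. Summed over the 6 classes, 10785 genes passed between W8 and M8 (4705 higher and 6080 lower). Between M8 and M12, 22332 passed (10851 higher and 11481 lower). The first count was 2863 without W8 replicate 1 and 5393 without W8 replicate 2. The second was 12570 without M12 replicate 1 and 13241 without M12 replicate 2. At M8, luteal cells were 17.3% ± 0.20 of barcodes, blood endothelial cells 16.1% ± 3.32 and stromal cells 11.6% ± 7.82. Without low-UMI clusters luteal cells were 8.61% and 9.29% in M8 replicates 1 and 2, and stromal cells 26.6% and 21%. Single genes of these steps are not described.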

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

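The list tests behind these values were planned, while the medians in 1 shared cluster per class come from an alternative chosen after the data were seen. In 9 cases list medians moved opposite ways in different classes. The list's mean level in both libraries of the later age lay on 1 side of both libraries of the earlier age, and no difference between classes was tested. Between D14 and W8, the cell cycle median was higher in endothelial cells (5 of 30 genes rose) and lower in theca (9 of 30 fell), 1.49 apart in log2 change. The ribosomal protein median was higher in macrophages and lower in stromal cells, 0.329 apart, but in macrophages 3 of 81 genes rose and the median was 0.02 after thinning, against 0.10. Between W8 and M12, the medians of steroid hormone synthesis and the transforming growth factor beta family were higher in granulosa cells and lower in macrophages (1.01 and 0.594 apart), where 0 of 17 and 0 of 26 genes passed. The immediate early and heat shock median was higher in luteal cells and lower in macrophages (1.48 apart), where 3 of 27 genes fell. The unfolded protein response median was higher in luteal and lower in granulosa cells (0.831 apart), and the follicle and luteal RNA median higher in granulosa and lower in endothelial cells (1.79 apart), where 4 of 13 genes fell. The cholesterol synthesis median was higher in theca and lower in luteal cells (1.27 apart), and the interferon response median higher in endothelial cells and lower in macrophages (1.08 apart), where 2 of 25 genes fell. With an estimated correlation none of the list calls passed (adjusted p = 0.186 to 0.514 between D14 and W8 and 0.374 to 0.709 between W8 and M12). In 1 shared cluster per class, the granulosa medians of steroid genes and follicle RNA were -0.02 and -0.20, against 0.39 and 0.37. The endothelial interferon median was -0.05 there, against 0.49, and the luteal medians of immediate early and unfolded protein response genes were 0.53 and 0.16, against 1.09 and 0.48.

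Other values lie in barcodes that no test used. Germ cell barcodes were 13.5% and 23.9% of the kept barcodes of D14 replicates 1 and 2, libraries described as somatic cells. Barcodes of unnamed clusters were 20.1% and 10.1% of W8 replicates 1 and 2 and 11% and 26.8% of M8 replicates 1 and 2. Most of them lie in cluster 9 (8582 barcodes), a low-UMI cluster with AY036118, Lars2 and Hsd17b1 among its top genes. At resolution 2, cluster 12 (4496 barcodes, 1954 and 743 of them in W8 replicates 1 and 2) is called granulosa, which gives granulosa shares of 46.6% and 40.8% there.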

How the results depend on the processing

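Tests under 3 of the alternatives were chosen after the data were seen (without low-UMI clusters, without both M8 libraries, one shared cluster only). Leaving out 1 library at a time, where the lone library of an age is assumed to vary like the others, gave 3658 to 6892 genes in granulosa, 2382 to 3850 in theca, 4300 to 7144 in stromal, 390 to 2850 in endothelial cells and 358 to 1124 in macrophages for W8 minus D14. For M12 minus W8 it gave 2987 to 4974 in granulosa, 818 to 2056 in theca, 4633 to 7656 in luteal, 3851 to 6749 in stromal, 720 to 4710 in endothelial cells and 18 to 351 in macrophages. It gave 2863 to 12798 for M8 minus W8, 12570 to 22685 for M12 minus M8, 3 to 7 and 4 to 8 classes by share, and 65 to 69 and 56 to 61 lists. Fewer libraries give fewer degrees of freedom, and the cause of the higher counts without an M8 library was not tested. Other moved counts for W8 minus D14 were 2770 in granulosa after thinning, which removes counts, 2005 in theca with DESeq2, 2038 and 1343 in endothelial cells and macrophages without a count filter, 2463 and 1338 there without low-UMI clusters, and 2766 in endothelial cells without both M8 libraries. For M12 minus W8 they were 768 in theca, 1904 in endothelial cells and 225 in macrophages with DESeq2, 1122 in theca with at most 10% mitochondrial UMIs, 3772 in luteal cells and 332 in macrophages in one shared cluster only, and 4642 and 410 in endothelial cells and macrophages without both M8 libraries. Macrophages also had 660 without a count filter, 45 after thinning, 198 with doublets kept, 54 at resolution 2, 332 without low-UMI clusters and 301 with a replicate block. Share tests called 11 classes with centred log ratios and 10 without low-UMI clusters for W8 minus D14, and 4 with TMM for M12 minus W8. Lists called were 0 and 0 with an estimated correlation and 36 with fry for M12 minus W8. At P1, at least 1000 genes gave 11% germ, 43.9% stromal and 20.3% erythroid cells, and at most 10% mitochondrial UMIs 15.1% epithelial cells. In one shared cluster only, 4 genes turned direction for M12 minus W8: Rhox8 (-1.08) and Cyp11a1 (-0.32) in granulosa, Rsad2 (-0.031) and Irf7 (-0.34) in endothelial cells. Apart from the construction named, the cause was not tested. Of 5295 values of 275 named genes, 4974 kept direction and call, 317 lost the call and 4 turned. Of 1370 values of 126 lists, 1163 kept the call and 207 lost it, 126 of these with an estimated correlation and 43 with fry. Of 190 values of 12 shares, 171 kept the call and 19 lost it. With DESeq2 the percent of called genes that rose went from 51.7 to 62.4 in endothelial cells for W8 minus D14 and from 49.98 to 38.4 for M12 minus W8, while medians of all genes moved by less than 0.1. Replicate numbers do not pair the libraries: differences between replicates correlated between ages at -0.18 to 0.24 across genes. With replicate number as a block, 6155, 3661, 6456, 1165 and 908 genes passed in granulosa, theca, stromal, endothelial cells and macrophages for W8 minus D14, and 4494, 1842, 6183, 2655 and 301 for M12 minus W8, with 6381 in luteal cells. Shares stayed at 5 and 7 classes with the block, lists were 69 and 59, and the summed counts 10571 and 21803. Simulated 1.5-fold changes were found least often in macrophages and endothelial cells (4.48% and 10.4% of genes), whose coefficients of variation are also the highest (0.155 and 0.127), and depth was not tested apart from spread.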

Other observations

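The tests of the smooth muscle and epithelial classes were chosen after their shares were seen, while the tests of technical explanations further on were written before their results were seen. Smooth muscle cells and pericytes differed in 3163 of 12283 genes between W8 and M12 (1616 higher and 1547 lower). They rose in Sncg, a synuclein (38.5 to 287 CPM, adjusted p = 1.33e-12), in Rcan2 (log2 2.97 ± 0.44), an inhibitor of calcineurin, and in the cell cycle inhibitor Cdkn1a (log2 2.76 ± 0.22). These cells lie in clusters whose sizes differ by age, and no test was run within one. Cluster 25 held 373 and 406 cells at W8 and 502 and 493 at M12, and cluster 17, with Sncg among its top genes, 167 and 154, then 821 and 728. At resolution 2, cluster 23, with Sncg and Rcan2 among its top genes, went from 57 and 57 cells to 738 and 643, so the rise of both may come from the mix of clusters. Epithelial cells differed in 367 of 11843 genes between W8 and M12 (161 higher and 206 lower). In them the protease inhibitor Serpina3g (log2 5.34 ± 0.33) rose, and Cldn10 (log2 -2.97 ± 0.43) fell.

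The rise of interferon and antigen presentation genes from D14 to W8 in granulosa, theca, stromal and endothelial cells could come from free RNA of immune cells, of which the labels name no sort or gate. Lyz2, abundant in macrophages (12962 CPM at W8), went from 0.529 to 14.4 CPM in theca. Scaled by the immune RNA of a class, free RNA would give at most 0.0376 of the observed rise of interferon and MHC class I genes (highest class median), and the lower oocyte RNA at W8 at most 0.0361, which argues against both. For MHC class II genes, free immune RNA would give 1.49 times the rise (median over granulosa, theca and stromal cells), so it may account for their rise there. Age, an unlabelled difference between library batches and a change in the mix of clusters within a class stay open for the rest. Age and batch cannot be told apart, and no test was run within a cluster shared by D14 and W8.

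The fall of ribosomal protein genes from W8 to M12 might follow from UMI depth or from a few genes taking more of the counts. Among cells of 5000 to 10000 UMIs, the list kept at least 50% of its median change in 4 of the 5 classes with at least 20 such cells in each library (not in theca, -0.14 against -0.31). Luteal cells were left out after the values were seen, having 27 such cells at M12. The list lay more than 0.1 below other genes of its abundance in 6 of 6 classes, by -0.25 to -0.89. Both values argue against these explanations, and age and an unlabelled batch difference stay open. The libraries of an age could also be draws of 1 pool of cells. Of 23 pairs of libraries, 18 differed by more than the highest of 20 random splits of their pooled cells, but separate capture and preparation of 1 pool would give this too, so the question stays open.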
